A study of Mus musculus with 12 samples.

How the data were processed

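Tumor blocks grown from MC38, a mouse colon adenocarcinoma cell line, were profiled by RNA sequencing after intravenous injection of vehicle or of BG136, a soluble β-1,3/1,6-glucan. Per the labels, total RNA was extracted and stranded poly(A) libraries were made with an Illumina kit. There were 6 vehicle and 6 BG136 libraries, each labelled with a number of its own within its group. The labels do not state that the samples came from separate animals, so p-values measure the spread between these samples. Those of the list test with a preset correlation, described below, do not measure that spread alone. No batch, date or tumor size was given in the sources used here.

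The authors deposited 1 table of 15170 genes. Its expression columns hold FPKM, fragments per kilobase scaled to library size, which the authors computed per library; the header calls them only expression, and the unit was taken from the values. Per the submitters' processing notes, Trimmomatic, HISAT2, Cufflinks, HTSeq and DESeq were used with the mouse build GRCm39; versions, order and annotation are not given in the sources used here. The deposited base mean columns hold a signal averaged over all libraries or over 1 group, which per the file headers the authors took from DESeq2 without pairing. The same deposited table gives a linear fold change, its log2 value, a p-value and a q-value for BG136 over vehicle. No mitochondrially encoded gene was listed, and the filter that left 15170 genes is not given in the sources used here.

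Within a library, the FPKM of a gene is a whole multiple of the value of 1 read. Scaling each gene to its deposited base mean gave read numbers of which 100% lay within 0.1 of a whole number, and the BG136 base mean recomputed from them differed from the deposited one by a fraction of at most 7.0e-08. On simulated data with 15170 genes the step recovered 100% of reads. The gene lengths this implies had a Spearman rho of 0.761 with exon lengths of another mouse build's annotation over 14730 genes matched by name. This is a correlation across genes, which are not independent replicates. Recovered depth was 14828786 to 18125931 reads in 10 libraries, and 33231037 and 32956232 reads in BG136 replicates 7 and 9. No coordinates are given, because the reference at hand was of another build than the table.

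Replicates were compared within groups by a chi-square of recovered reads over genes with at least 20 reads in the pair. BG136 replicates 7 and 9 gave 0.285 per gene over 13819 genes, less than sampling noise, against 7.88 to 57.4 in the other 29 pairs. Their mean FPKM was therefore used as 1 sample, leaving 5 BG136 and 6 vehicle samples. The fit fixed before the data were examined counted all 12 libraries separately; counting these 2 as 1 sample was decided after seeing the data, and the fit of all 12 libraries is given beside it.

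Values were tested as log2(FPKM + 1), so fold changes are on that scale and understate the change of low genes. Genes with FPKM of at least 1 in at least 6 samples were kept, which left 11356. The test was limma's moderated linear model with a mean-variance trend (limma 3.58.1, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05; every adjusted p for a gene comes from it unless another tool is named. The plan assumed counts and named this test for a table of FPKM. On simulated reads of this comparison (5 against 6, 11348 genes), the same steps called 90% of genes changed 2-fold and 96% of genes changed 4-fold, with 9 unchanged genes called. The simulation planted many changed genes and drew each gene independently. Its shares therefore do not show that the real fit would find a 2-fold change. In the real fit Cidec, with group means 2.45-fold apart, had an adjusted p of 0.978.

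Of 35 gene lists fixed before the data were examined, the 32 with at least 5 tested members were tested. NK cells (3 tested), keratinocytes and skin (3) and mitochondrially encoded genes (0) had too few. The list test was limma's camera with a preset correlation of 0.01, two-sided, adjusted over the lists, and was repeated with an estimated correlation and with fry, a rotation test of whether a list's genes move one way. The preset takes members of a list as almost independent of each other. Estimated correlations ran from -0.0688 (nerve cells) to 0.855 (T cells), with 0.393 for adipocyte, 0.821 for ribosomal and 0.666 for oxidative phosphorylation genes. Where the estimate is well above 0.01, the preset p reflects how many correlated members a list holds and is too small. A list score is the mean over members of a sample's log2 value minus the gene's mean over samples; it was compared between groups by an exact two-sided permutation test over the 462 splits of 11 samples.

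Genes named in the text follow a rule fixed before the data were examined. First, 12 genes of glucan signalling and tumor immunity were named whatever their values. In each direction up to 8 genes past the threshold with the largest changes were named, or, where fewer than 4 passed, the 6 with the smallest p. These needed a mean FPKM of at least 1, and unnamed gene models were left out. Last came the 3 members with the smallest p of each list past the threshold. For 2 of these lists 1 such member is not reported here. The other settings fixed before the data were examined were no filter, a pseudocount of 0.1, sample weights, robust moderation, an adjusted p under 0.1, each library left out, and the sample number as a block. Settings chosen after seeing the data were limma's voom on recovered reads, median-ratio scaling, removal of each library's trend on gene length (lowess, span 0.3), vehicle replicates 11 and 12 left out, and the exact test of list scores. Relations between list scores used 100000 within-group permutations in numpy 2.4.6 and scipy 1.17.1.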

Results

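The study asked how BG136 given alone alters gene expression in MC38 tumors, as part of work that combined it with antibodies against PD-1, an inhibitory receptor of T cells. RNA of tumor blocks from mice injected intravenously with vehicle (6 libraries) or BG136 (6 libraries) was compared in FPKM. BG136 replicates 7 and 9 differed by less than the sampling noise and were counted as 1 sample, so n was 5 for BG136 and 6 for vehicle. Depth was 14828786 to 18125931 recovered reads in the other 10 libraries and 33231037 and 32956232 in these. Values below are mean FPKM ± SD.

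Genes of fat cells were lower in BG136 tumors. Adipoq, which encodes the hormone adiponectin, was at 2.13 ± 1.36 (SD, n = 5) in BG136 tumors and 5.58 ± 1.95 (SD, n = 6) in vehicle tumors. Cidec, a lipid droplet protein, was at 1.40 ± 0.82 against 3.42 ± 0.56. Plin1 and Plin4, which coat lipid droplets, were at 0.756 ± 0.525 against 2.21 ± 0.81 and at 0.945 ± 0.620 against 2.21 ± 0.57. All 10 tested members of the adipocyte list were lower, with a median log2 fold change of -0.77, and the list fell in camera (adjusted p = 3.7e-23 with the preset correlation, adjusted p = 0.0224 with an estimated correlation). Its score was lower in each of the 5 BG136 samples than in any of the 6 vehicle samples (exact permutation p = 0.00216, the smallest the design allows; 0.0693 after adjustment over 32 lists). The scores were -0.097, -0.691, -0.742, 0.094 and -0.687 in BG136 replicates 1, 2, 4, 6 and 7-9, and 0.179 to 0.76 in vehicle samples. In the same BG136 order the T cell scores were -0.304, 0.373, 0.242, -0.889 and 0.396, those of MHC class II genes -0.347, 0.605, 0.372, -0.585 and 0.417, and those of skeletal muscle genes -1.477, 0.657, 1.694, -0.249 and 0.708. Vehicle replicates 1, 2, 3, 7, 11 and 12 had adipocyte scores of 0.349, 0.344, 0.179, 0.245, 0.76 and 0.248. Their T cell scores were 0.06, -0.217, 0.186, 0.092, 0.232 and -0.172, and those of MHC class II genes -0.306, -0.12, 0.011, 0.225, -0.172 and -0.101. Their skeletal muscle scores were -1.355, -1.203, 2.181, -1.002, 1.461 and -1.415. No member of the adipocyte list passed over all genes, and 9 passed adjusted over the list alone. The adipocyte median was -1.35 with a pseudocount of 0.1 and -1.52 with voom on recovered reads. With the estimated correlation the call was lost without vehicle replicate 1 (adjusted p = 0.0934), 2 (0.0704) or 3 (0.065), or without BG136 replicate 2 (0.141) or 7-9 (0.052).

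**Figure D1:**
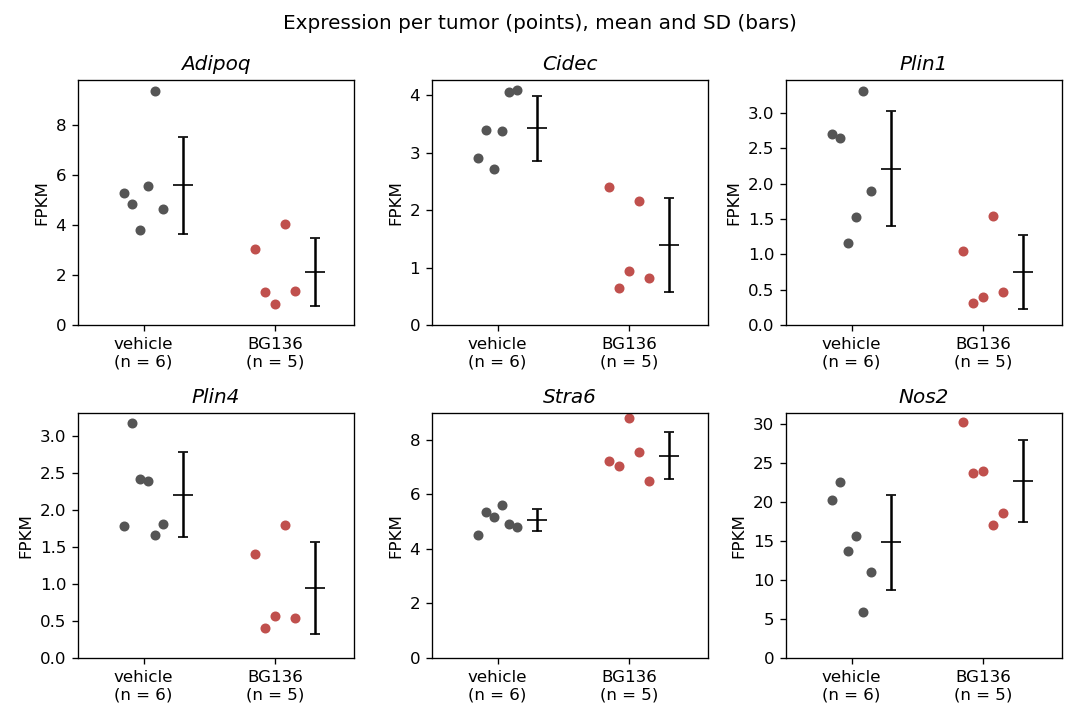
FPKM (vertical axis, linear, from 0) of 6 genes in 6 vehicle and 5 BG136 samples. Points are samples and bars are mean and SD. Cidec lay at 0.653 to 2.41 in BG136 and 2.72 to 4.08 in vehicle samples, and Stra6 at 6.50 to 8.79 and 4.52 to 5.63. The ranges of the groups overlapped for Adipoq (0.870 to 4.04 and 3.79 to 9.36), Plin1 (0.317 to 1.54 and 1.16 to 3.31), Plin4 (0.411 to 1.80 and 1.66 to 3.175) and Nos2 (17.0 to 30.25 and 5.85 to 22.5).

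No single gene passed the threshold. Of 11356 genes tested with limma, 0 had an adjusted p under 0.05, 0 had one under 0.1, and 233 had an unadjusted p under 0.05 (105 higher, 128 lower in BG136 tumors). These 233 are fewer than chance alone gives on average at that p. voom on recovered reads, chosen after seeing the data, also called 0, with 287 at an unadjusted p under 0.05, and the planned fit of all 12 libraries called 0, with 443. The lowest adjusted p was that of Stra6, a membrane receptor for retinol-binding protein, at 7.42 ± 0.86 (SD, n = 5) in BG136 and 5.07 ± 0.40 (SD, n = 6) in vehicle tumors, a log2 difference of 0.47 (95% interval 0.30 to 0.64; adjusted p = 0.477). The next smallest p among genes higher in BG136 tumors belonged to the scavenger receptor Scara5 (4.36 ± 1.67 against 2.23 ± 0.73), the interferon-induced Ifit2 (24.3 ± 0.5 against 20.2 ± 2.4), the cytokine Lif (4.46 ± 0.57 against 3.45 ± 0.35), Dpy19l1 (14.4 ± 0.5 against 12.6 ± 0.5) and Gas7 (6.91 ± 1.24 against 4.87 ± 1.05). Among lower genes, beside Cidec, Adipoq, Plin1 and Plin4, it belonged to Sncg, a synuclein (2.05 ± 0.63 against 3.96 ± 1.06), and the histone gene H2ac15 (0.646 ± 0.319 against 1.51 ± 0.44), which may share reads with other histone genes. None of these passed; apart from Stra6 each had an adjusted p of 0.978.

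The authors' deposited table gives a q-value under 0.05 to 9 genes, 2 higher and 7 lower in BG136 tumors, and a p-value under 0.05 to 766. In the authors' deposited table the 9 were Adrb3 (log2 fold change -2.22, q = 5.62e-05), Trarg1 (-0.92), Cidec (-1.42), Gpd1 (-1.28), Plin1 (-1.67), Adipoq (-1.50) and Car3 (-0.92), and higher Stra6 (0.50) and Cyp26b1 (0.85). The BG136 base mean of the authors' deposited table was matched with replicates 7 and 9 entered separately. Adrb3, Trarg1, Gpd1 and Cyp26b1, named here because of that table, lay under the filter. Without the filter, limma gave Adrb3 a log2 difference of -0.374 and an adjusted p of 0.173. The log2(FPKM + 1) scale shrinks the change of so low a gene, so these values are not like the authors' DESeq2 values. The fits of recovered reads kept the filter, so Adrb3 was not tested in them.

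The receptor and signalling genes through which β-glucans are known to act did not pass the test. Clec7a, which encodes the β-glucan receptor Dectin-1, was at 48.3 ± 26.9 (SD, n = 5) in BG136 and 36.5 ± 12.2 (SD, n = 6) in vehicle tumors, with a log2 difference of 0.31 (95% interval -0.38 to 1.01; limma adjusted p = 0.978). For Clec7a the difference was 0.124 without vehicle replicate 11, 0.041 without vehicle replicates 11 and 12, 0.042 without BG136 replicate 2, 0.536 without BG136 replicate 6 and 0.097 with sample weights. Its downstream kinase Syk was at 5.04 ± 0.63 against 4.57 ± 1.09, and the adaptor Card9 at 6.83 ± 0.93 against 5.88 ± 0.99. Itgam and Itgb2, the chains of complement receptor 3, were at 33.7 ± 5.2 against 29.6 ± 6.3 and at 69.8 ± 15.2 against 66.3 ± 8.3. The sign of the difference turned without vehicle replicates 11 and 12 for Syk, Itgam and Itgb2. Of the 19 tested genes of the β-glucan receptor and C-type lectin list, 14 were higher and 5 lower, with a median log2 fold change of 0.075, and the list did not pass (adjusted p = 0.179). It passed without BG136 replicate 6 (adjusted p = 0.00233) and with the gene length trend removed (adjusted p = 0.0467), both with the preset correlation. With an estimated correlation it did not pass (adjusted p = 0.774), and in both of those settings the adipocyte list was the 1 list past the threshold.

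Genes of T cells and checkpoints did not pass the test either. Cd8a, a marker of cytotoxic T cells, was at 14.2 ± 6.2 in BG136 and 13.3 ± 3.0 in vehicle tumors, and the sign of its difference turned with some samples left out, as it did for Pdcd1, Cd274 and Ifng. Pdcd1, which encodes PD-1, was at 3.84 ± 1.56 against 4.48 ± 1.40, its ligand Cd274 at 32.0 ± 8.5 against 30.6 ± 9.1, and interferon-γ (Ifng) at 3.24 ± 1.94 against 2.62 ± 0.28. The list of T cells had a median log2 fold change of -0.07 (adjusted p = 0.13), interferon-γ response genes 0.027 (0.824), checkpoints 0.036 (0.578), regulatory T cells -0.037 (0.59, with a mean of 0.001, opposite in sign), MHC class I genes -0.023 (0.435) and MHC class II genes 0.173 (0.0648).

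Macrophage, mast cell and granzyme lists rose with the preset correlation, and none of these calls held with an estimated one. Of 100 splits of the samples, 56 gave as many lists past the preset threshold as the 12 found here. In the list of alternatively activated macrophages 16 of 17 members were higher, with a median of 0.21 (adjusted p = 2.16e-04; adjusted p = 0.545 with an estimated correlation). The mannose receptor Mrc1 was at 24.6 ± 6.0 against 19.3 ± 6.7, the interleukin-4 receptor chain Il4ra at 24.6 ± 0.9 against 21.5 ± 1.7, and the PD-1 ligand gene Pdcd1lg2 at 3.56 ± 2.29 against 2.00 ± 1.11. Of 20 monocyte and macrophage genes 17 were higher, with a median of 0.092 (adjusted p = 0.0268, and adjusted p = 0.746 with an estimated correlation). Examples were Ccr2 (13.9 ± 3.1 against 10.9 ± 2.5) and the growth factor receptor Csf1r (76.6 ± 7.9 against 67.4 ± 7.7). Nos2, an enzyme of classically activated macrophages, was at 22.7 ± 5.2 against 14.8 ± 6.1, while that list did not pass (median 0.117; adjusted p = 0.0789). Without vehicle replicates 11 and 12 the log2 difference went from 0.661 to 0.315 for Nos2 and from 0.359 to 0.181 for Mrc1. Of 7 genes of mast cells, basophils and eosinophils 6 were higher, with a median of 0.46 (adjusted p = 0.00506, and adjusted p = 0.545 with an estimated correlation); without the filter the median was 0.08 (adjusted p = 0.024). The mast cell proteases Tpsb2, Cma1 and Cpa3 were at 12.7 ± 5.0 against 7.01 ± 2.30, 5.05 ± 2.02 against 2.99 ± 1.03 and 3.54 ± 1.59 against 2.17 ± 0.46. Of 17 cytotoxic effector genes 15 were higher, with a median of 0.14 (adjusted p = 0.021, and adjusted p = 0.774 with an estimated correlation). The granzymes Gzmc, Gzmg and Gzmd, which are related genes that may share reads, were at 14.9 ± 5.1 against 8.65 ± 3.54, 10.5 ± 7.6 against 5.14 ± 5.14 and 8.40 ± 5.65 against 4.57 ± 3.68, and Gzmb at 31.3 ± 10.9 against 26.5 ± 5.2.

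Lists of protein synthesis, energy metabolism and proliferation fell by small amounts with the preset correlation, and none of these calls held with an estimated one. All 24 cytosolic ribosomal protein genes were lower, with a median of -0.16 (adjusted p = 1.73e-15, and adjusted p = 0.545 with an estimated correlation). Examples were Rplp1 (2532 ± 229 against 3129 ± 470) and Rps18 (1429 ± 86 against 1682 ± 169). All 21 oxidative phosphorylation genes were lower, with a median of -0.12 (adjusted p = 3.75e-09, and adjusted p = 0.545 with an estimated correlation). Examples were Atp5o (212 ± 7 against 245 ± 35), Cox7a2 (84.5 ± 7.6 against 101 ± 19) and Ndufa2 (98.1 ± 9.5 against 115 ± 20). Vehicle replicates 11 and 12 stood apart in both lists, with ribosomal scores of 0.29 and 0.29 against -0.07 to 0.02 in the other vehicle samples; without them the ribosomal median was -0.07 and the oxidative phosphorylation median was -0.01 and did not pass (adjusted p = 0.115). The sign of the oxidative phosphorylation and erythroid medians turned in the 6 samples with shared numbers. Glycolysis and hypoxia genes were lower in 18 of 23, with a median of -0.08 (adjusted p = 0.0261, and adjusted p = 0.774 with an estimated correlation). Examples were Pkm (449 ± 28 against 488 ± 43), Eno1 (848 ± 83 against 924 ± 84) and Tpi1 (573 ± 61 against 627 ± 67). Cell cycle genes were lower in 17 of 25, with a median of -0.03 (adjusted p = 0.0132, and adjusted p = 0.746 with an estimated correlation). Examples were Mcm5 (49.5 ± 5.6 against 55.2 ± 3.6), Aurkb (37.2 ± 2.3 against 40.5 ± 2.3) and Pcna (182 ± 15 against 199 ± 10).

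Immediate early and heat shock genes, which respond to stress and handling, were lower in 16 of 20, with a median of -0.12 (adjusted p = 0.0121, and adjusted p = 0.746 with an estimated correlation). Dnajb1 was at 27.2 ± 5.6 against 35.8 ± 6.4, Ier2 at 23.9 ± 2.5 against 28.5 ± 3.4 and Hspa1b at 10.1 ± 5.1 against 22.1 ± 20.5. In vehicle replicate 2 Hspa1b was at 62.0 and in the other vehicle samples at 9.20 to 26.6; its log2 difference was -0.87, and -0.51 without that replicate. Erythroid genes were lower in 5 of 6, with a median of -0.16 (adjusted p = 0.0261, and adjusted p = 0.545 with an estimated correlation). Examples were the hemoglobin genes Hbb-bs and Hbb-bt, near-identical copies that can share reads, at 12.4 ± 2.6 against 15.9 ± 4.4 and 1.66 ± 0.59 against 2.48 ± 1.11, and Bpgm at 12.8 ± 0.8 against 14.4 ± 3.4. Epithelial genes were lower in 5 of 8, with a median of -0.40 (adjusted p = 0.0277, and adjusted p = 0.746 with an estimated correlation). In BG136 replicates 4 and 6 Krt18 was listed at 0 and Krt19 at 0.084 and 0.089, while Krt19 lay at 3.89 to 11.9 in the other BG136 and 5.73 to 9.78 in the vehicle samples, and Epcam was at 0.637 ± 0.530 against 1.27 ± 0.47.

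The other lists did not pass the preset test. Their median log2 fold changes were -0.058 for endothelial cells (adjusted p = 0.0648), 0.054 for NF-kB cytokines (0.13), 0.114 for dendritic cells (0.16), -0.012 for complement (0.435), 0.045 for apoptosis and p53 targets (0.439), -0.004 for interferon-stimulated genes (0.45, with a mean of 0.032, opposite in sign), 0.051 for chemokines (0.45), 0.048 for fibroblasts and matrix (0.462, mean -0.012), -0.044 for neutrophils (0.51), 0.03 for nerve cells (0.578), 0.488 for skeletal muscle (0.578) and 0.019 for B and plasma cells (0.991, mean -0.03). Outside the adipocyte list 1 gene passed adjusted over the list alone, Cfd of the complement list, which is also an adipocyte gene, and 0 passed over all genes.

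With the preset correlation the adipocyte, ribosomal, oxidative phosphorylation, alternatively activated macrophage and mast cell lists passed without any 1 library. Among these the oxidative phosphorylation median was -0.07 without vehicle replicate 11, the alternatively activated macrophage median 0.323 without vehicle replicate 1, and the mast cell median 0.301 without BG136 replicate 4. The monocyte and macrophage list was lost without vehicle replicate 1 or 2 or BG136 replicate 2, 4 or 7-9 (adjusted p up to 0.306); its median was 0.05, 0.054 and 0.054 without vehicle replicate 1, vehicle replicate 2 and BG136 replicate 7-9, and 0.155 and 0.162 without BG136 replicates 1 and 6. The cytotoxic list was lost without vehicle replicate 2 or 3 or BG136 replicate 2, 4 or 7-9 (up to 0.67). Its median was 0.027, 0.075 and 0.053 without those BG136 replicates, and 0.221 and 0.356 without BG136 replicates 1 and 6. The epithelial list was lost without vehicle replicate 1, 3 or 7 or BG136 replicate 4, 6 or 7-9 (up to 0.318), with medians of -0.251 and -0.227 without BG136 replicates 4 and 6 and -0.661 without BG136 replicate 2. The erythroid list was lost without vehicle replicate 3 or 11 or BG136 replicate 1 or 2 (up to 0.112). Its median was -0.059 without vehicle replicate 11, -0.1 without BG136 replicate 1, and -0.233, -0.242 and -0.253 without vehicle replicate 2, vehicle replicate 7 and BG136 replicate 2. The cell cycle list was lost without vehicle replicate 2 or 3 or BG136 replicate 1 or 6 (up to 0.277); its median was 0.005 and -0.004 without BG136 replicates 1 and 6, and -0.048, -0.07 and -0.047 without vehicle replicate 1, BG136 replicate 2 and BG136 replicate 7-9. The glycolysis list was lost without vehicle replicate 1, 2, 7 or 12 or BG136 replicate 2, 4 or 7-9 (up to 0.575). Its median was -0.046 without vehicle replicate 1, -0.019, -0.032 and -0.018 without those BG136 replicates, and -0.132 and -0.139 without vehicle replicate 3 and BG136 replicate 6. The immediate early list was lost without vehicle replicate 1 or 2 or BG136 replicate 2 or 4 (up to 0.315), with medians of -0.052, -0.062 and -0.082 without vehicle replicate 2, vehicle replicate 11 and BG136 replicate 2. For the β-glucan receptor list the median was 0.042 without BG136 replicate 2 and 0.125 without BG136 replicate 6.

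Other settings ended further preset calls. Without vehicle replicates 11 and 12 the cytotoxic (adjusted p = 0.0793), monocyte and macrophage (0.0933) and erythroid lists (0.416, median -0.009) did not pass either. The median was then 0.12 for alternatively activated macrophages, -0.077 for immediate early genes and 0.012 for the β-glucan receptor list. With the gene length trend removed the epithelial (0.108), erythroid (0.194, median -0.078), glycolysis (0.0739) and immediate early lists (0.0675) did not pass. The ribosomal, oxidative phosphorylation, cell cycle and β-glucan receptor medians were then -0.091, -0.073, -0.043 and 0.049. Sample weights ended the erythroid call (0.223, median -0.058) and gave medians of -0.071 for oxidative phosphorylation, 0.21 for cytotoxic, -0.671 for epithelial, -0.131 for glycolysis and 0.157 for monocyte and macrophage genes. Median-ratio scaling ended the epithelial call (0.0619) and gave a cell cycle median of -0.044. The epithelial median was -0.192 without the filter, -1.16 with a pseudocount of 0.1 and -1.51 with voom on recovered reads, which gave -0.042 for cell cycle genes. In voom with all 12 libraries the medians were -1.64 for adipocyte, 0.278 for cytotoxic, -1.46 for epithelial and 0.724 for mast cell genes.

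**Figure D2:**
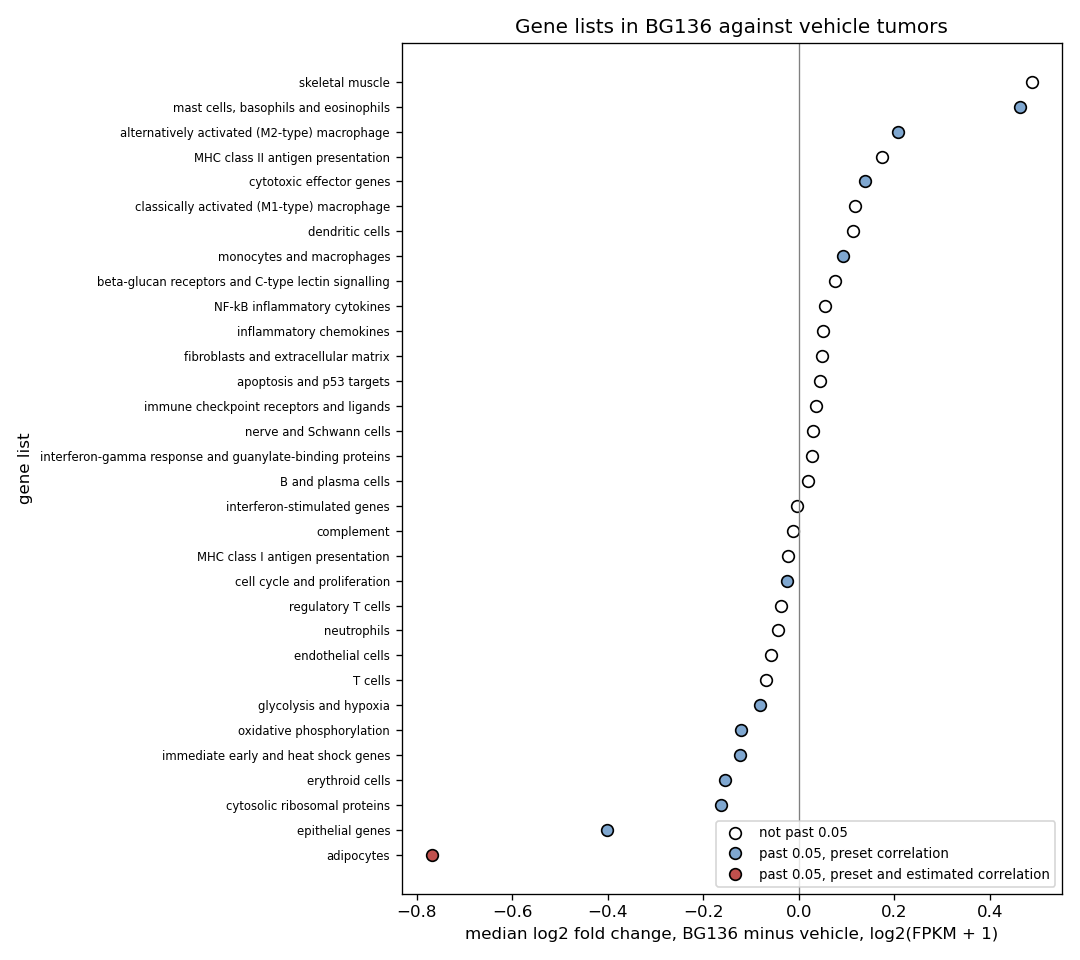
Median log2 fold change, BG136 minus vehicle (horizontal axis, log2(FPKM + 1) scale), of 32 gene lists (vertical axis). Each point is a list, with filled points for lists past 0.05; the adipocyte list, at -0.77, is the 1 list that also passed with an estimated correlation.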

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

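The tests of replicates 7 and 9, of fat tissue, of a single library and of vehicle replicates 11 and 12, and the count of splits for genes, were chosen after the result was seen; those of gene length and the counts of splits for gene lists were fixed before their results were seen, that with an estimated correlation after the other counts of splits were known.

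BG136 replicates 7 and 9 were almost equal. Separately sequenced libraries differ by at least sampling noise, a chi-square per gene near 1 or above, and 0.285 argues against that whatever RNA they came from. The value is one that columns sharing most of their reads would give, so the columns may hold overlapping reads. Both had close to the same high depth, 1.95 and 1.93 times the median of the other 10 libraries, and whether they hold 1 tumor or reads of 2 was not tested. No biological explanation was tested.

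The lower adipocyte genes were weighed next. Removing each library's trend on gene length left the median at -0.78, which argues against length bias, and without any 1 library it was at most -0.69, which argues against a single library as the whole of the difference. The call with an estimated correlation was nonetheless lost in 5 of the 11 fits with 1 library left out (adjusted p = 0.052 to 0.141). The mean pairwise correlation of members within groups was 0.39, at 0.405 among BG136 and 0.292 among vehicle samples. The last lay under 0.3, the cut of a test chosen after the result was seen. A higher value could not have decided either, because members could also move together under an effect of BG136 on fat cells. Nor does a correlation within groups bear on the difference between them. Different amounts of fat tissue in the tumor blocks therefore cannot be told apart from an effect of BG136 on fat cells, which is untested.

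The lower ribosomal and oxidative phosphorylation genes could not be settled. Over the 45 genes of both lists the median log2 fold change was -0.14. It was -0.05 without vehicle replicates 11 and 12 and -0.087 with the length trend removed, so neither explanation can be told apart from a treatment difference. When genes were put into 4 classes of length, the shortest deviated from the group mean by 0.158 and the longest by -0.169 in those replicates (median log2).

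Chance cannot be excluded for the count of lists with the preset correlation. Of 100 splits of the 11 samples into 5 and 6, the real one included, 56 gave at least the real 12 lists (highest other 25). For genes the count decides nothing, because all 100 splits reach a real count of 0 (highest other 23). With an estimated correlation 3 of 100 gave at least the real 1 list (highest other 1), a share under 5%, but the exact binomial 95% interval of the 2 in 99 other splits reaches 7.11%, so chance is not firmly excluded. The count was 0 without vehicle replicate 1, 2 or 3 or BG136 replicate 2 or 7-9. It was also 0 with the exact test of list scores (adipocytes, adjusted p = 0.0693), which decides nothing here. The smallest exact p this design allows, 0.00216, becomes 0.0693 after adjustment over 32 lists where only 1 list reaches it. Of the 99 other splits 4 called any gene, and 55 of all 100 had at least the real 233 genes at an unadjusted p under 0.05. The highest of the others, 23 genes called in 1 split and 3262 at that p in another, are extremes picked from 99. The split with 23 put vehicle replicates 3 and 11 with BG136 replicates 2, 4 and 7-9, the samples with positive skeletal muscle scores. It was also 1 of the 2 other splits with a list past the threshold with an estimated correlation. Whether the samples have a structure that does not follow the groups was not tested.

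A sample lay far from the others of its group in 7 of 138 groups of values looked at, and chance flags about 1 in 20. BG136 replicate 6 was low for Cd274 (17.4 FPKM) and for the β-glucan receptor list (score -0.28). Vehicle replicate 11 was high for Sncg (6.06 FPKM) and for the adipocyte list (score 0.76). Vehicle replicate 2 was high for H2ac15 (2.37 FPKM), vehicle replicate 3 low for Ier2 (22.3 FPKM) and vehicle replicate 1 high for the list of alternatively activated macrophages (score 0.38).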

How the results depend on the processing

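Settings with voom, median-ratio scaling, the length trend removed, vehicle replicates 11 and 12 left out, and the exact test of list scores were chosen after seeing the data, as was counting BG136 replicates 7 and 9 as 1 sample. Of 1798 values recomputed for the counts, the named genes, the 12 lists and the β-glucan receptor list, 1682 kept their direction and side of the threshold or, for counts, stayed near the main one. Counts of 8 to 18 lists were taken as near 12. Most of the values were of named genes, none of which passed in the main fit. The count of genes past the threshold was 0 under every setting run. The count of 12 lists was 1 with an estimated correlation, 1 with fry and 0 with the exact test of list scores. With these sample sizes 1 list alone cannot pass the exact test after adjustment. The count of lists ranged from 7 to 20 when 1 library was left out, the lowest without vehicle replicate 2 and the highest without BG136 replicate 6. The adipocyte median then ranged from -0.91 to -0.69. Leaving out BG136 replicate 7 or 9 used the other in place of their mean.

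The sample numbers 1, 2 and 7 occur in both groups, and the deviations of same-numbered samples correlated at 0.488, -0.42 and 0.26. Samples numbered 1 and 7 correlated best with their own number, and those numbered 2 did not. So few correlations cannot show whether the numbers mark pairs, which the labels do not state. With these numbers as a block, in 6 samples and with genes at the minimum in at least 3, 0 genes and 18 lists passed, the same numbers as without the block in those samples. In both fits 12 of the 18 lists rose, against 4 of the 12 called in the main fit. The medians in both were -0.054 for ribosomal, 0.331 for cytotoxic and -0.193 for glycolysis genes. Of the 12 lists called in the main fit, 5 did not pass with the block or without it: alternatively activated macrophages (adjusted p = 0.0657 and 0.0504), epithelial genes (0.793 and 0.733, median -0.027), cell cycle genes (0.207 and 0.148), erythroid genes (0.765 and 0.855) and oxidative phosphorylation (0.989 and 0.822). In both of these fits the sign turned for Syk (-0.015), Pdcd1 (0.093), Cd274 (-0.025), Cd8a (0.275), Bpgm (0.04), Cox7a2 (0.013), erythroid genes (0.022) and oxidative phosphorylation (0.013).

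Sample weights turned Cd274 (-0.049) and Cd8a (0.09); all 12 libraries turned Cd8a (0.068; 0.07 with voom). Without vehicle replicates 11 and 12 the sign turned for Syk (-0.053), Itgam (-0.007), Itgb2 (-0.059), Cd274 (-0.208) and Bpgm (0.051). With 1 library left out, the value ranged from -0.165 to 0.269 for Cd8a, -0.09 to 0.272 for Cd274, -0.101 to 0.336 for Ifng, -0.027 to 0.195 for Itgb2, -0.35 to 0.016 for Pdcd1 and -0.07 to 0.005 for cell cycle genes. The cause was not tested for any of these turns, and fewer samples entered where libraries were left out. The settings planned for a table of counts (other scalings of counts and count models) were not run on the recovered reads, for which voom was added. The filter and the log2(FPKM + 1) scale limit low genes: Adrb3 and Cyp26b1 lay under 1 FPKM in every sample.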

Other observations

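The relations between gene lists below were chosen after the scores were seen.

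Skeletal muscle genes varied between tumor blocks far more than between groups. The muscle actin Acta1 was at 114 FPKM in vehicle replicate 3 and 67.4 in vehicle replicate 11, but at 0.147 to 1.68 in the other 4 vehicle samples; in BG136 samples it was at 0.212, 21.6, 81.5, 9.90 and 34.5 in replicates 1, 2, 4, 6 and 7-9. The creatine kinase Ckm followed, at 29.7 and 14.2 in vehicle replicates 3 and 11 and at 22.4 in BG136 replicate 4. Among epithelial genes, Krt8 was listed at 0 in BG136 replicate 4 and was at 0.14 in replicate 6, against 1.32 to 7.02 in the other BG136 and 2.00 to 6.67 in the vehicle samples, while Cdh1, which encodes E-cadherin, was at 4.41 and 2.84 in the same replicates 4 and 6.

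Scores of T cell genes, taken as deviations from the group means over 11 samples, went with those of MHC class II genes (Pearson r 0.861, permutation p = 0.0185, adjusted 0.0423; Spearman rho 0.818, p = 0.0368, adjusted 0.0671; 3 relations computed). Without the 2 samples farthest from the median, BG136 replicates 6 and 7-9, r was 0.726. The relation with interferon-γ response genes (r 0.794, permutation p = 0.0282, adjusted 0.0423; rho 0.745, p = 0.0519, adjusted 0.0671) rests on those samples, since r was 0.394 without them. With adipocyte genes r was -0.71 (permutation p = 0.0571) and rho -0.745 (p = 0.0671, adjusted 0.0671), and r was -0.42 without those samples. This relation with adipocyte genes did not pass. Vehicle replicates 1, 2, 3, 7, 11 and 12 had T cell scores of 0.06, -0.217, 0.186, 0.092, 0.232 and -0.172. Their adipocyte scores were 0.349, 0.344, 0.179, 0.245, 0.76 and 0.248, so the highest of both lay in replicate 11. In the same vehicle order MHC class II scores were -0.306, -0.12, 0.011, 0.225, -0.172 and -0.101, and interferon-γ response scores 0.14, 0.011, 0.1, 0.185, -0.403 and -0.143. T cell scores had an SD of 0.555 among BG136 and 0.185 among vehicle samples, so each pooled r rests mostly on BG136 samples. No r was computed within a single group, so none of these relations is shown for vehicle samples. The lists of each pair share 0 genes. Adjustment covered these 3 relations, not the other pairs of lists they were picked from.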
